A study of Sus scrofa with 6 samples.

How the data were processed

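Small RNA libraries were made from skin of Xiang pigs. Per the labels' protocols, the skin was disinfected with alcohol and freed of hair, kept in a preservative at low temperature, and a small RNA library kit for Illumina sequencing was used. The samples were grouped by the skin colour in the labels, with 3 white and 3 black libraries. The labels give no animal, body site, sex, age, batch or pairing, and the library codes are not shared between the groups, so no block was fitted.

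The authors deposited 1 table of miRNA values in RPM, reads scaled to a fixed total, a unit read from the values, since each column sums to 1e+06. Bowtie, with no version, and build Sscrofa11.1 are named in the submitters' processing notes without a role. The counting tool, the miRNA database release, the tool behind the predicted identifiers and the filters are not given in the sources used here. In every library 100% of the values were whole multiples of the worth of 1 read (tolerance 0.001), so reads were recovered. They numbered 7300193 (S02), 6454685 (S06) and 10165949 (S07) in white skin and 7745863 (S03), 7332769 (S04) and 8647930 (S05) in black skin. In RPM 1 read is worth 0.0984 to 0.155, and 3 reads, the limit that a count of 0 allows, 0.295 to 0.465. Such limits and all counting intervals cover counting error only, since reads after PCR are not independent molecules. RPM are shares of the listed miRNA reads, so a change in an abundant miRNA shifts all others. All 6 columns of values were used and 0 were left out.

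The design fixed before the data were examined named edgeR on counts, with limma if the table held none. As the deposited unit is RPM, the main test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(RPM + 1), black minus white, with Benjamini-Hochberg adjustment over all tested miRNAs and a threshold of 0.05. A fold change is on that scale and understates the change of scarce miRNAs. miRNAs were tested where edgeR 4.0.16's filterByExpr kept the recovered reads (minimum count 10, minimum total 15), which left 454 of 898 and at least 99.98% of the reads of each library. Single values were compared with a two-sided exact permutation test, whose smallest p is 0.1 with 3 against 3. On simulated libraries with 200 of 454 miRNAs changed, limma recovered 44.2% of 2-fold and 90.8% of 4-fold changes, with 2.6% false calls, over 20 runs. These runs averaged 139 calls, against 32 in the real data, and drew each miRNA independently. More calls make the adjusted threshold easier to pass, so recovery in the real data can be lower. With none changed it made 0.3 calls per run on average.

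Before the data were examined, 14 miRNA lists were fixed: pigmentation-linked, melanocyte-enriched, epithelial and keratinocyte, fibroblast and mesenchymal, HOX-cluster, striated muscle, vascular wall, erythroid, leukocyte, neural, liver and gut, let-7 family, miR-17-92 and paralogous clusters, and DLK1-DIO3 imprinted cluster. They were tested with limma's camera at a preset correlation of 0.01, repeated with an estimated correlation and with fry. Members were matched by name without arm or copy number. Lists overlap: 17 of the 24 pigmentation-linked and 4 of the 6 vascular wall members are in another list. In simulations, a list of 5 members lowered 4-fold passed in 20 of 20 runs and lists of 5 and 12 unchanged members in 0 and 1. Members were drawn independently there, so these runs do not show how often lists of correlated members pass.

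The miRNAs named in the text were chosen by a rule fixed at the same time. It takes all products of miR-221 and miR-222, up to 12 called in each direction with a miRBase-style name, the largest difference and no overlap between groups, and the 10 most abundant. It adds up to 2 predicted miRNAs called in each direction, and in each list the 3 most abundant and up to 6 called members. Outside the rule, chosen after their values were seen, are ssc-miR-24-2-5p, ssc-miR-204, ssc-miR-206, unconservative_1_93424, the cluster of miR-424, miR-503, miR-542 and miR-450 and the arm ratios with the miRNAs in them. Predicted identifiers are printed as in the table, which gives no sequence for them. Precursor coordinates and neighbouring genes were taken from a RefSeq gene table of Sscrofa11.1, which held a precursor for 265 of the 280 named miRNAs. No genome sequence was used here.

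Duplicate libraries were looked for with a chi-square test of recovered reads over miRNAs, and the smallest chi-square per degree of freedom of any pair was 303, so all 6 were kept. There were 47 rows with values identical to another row, 17 of them tested and 0 called. ssc-miR-199a-3p and ssc-miR-199b-3p, ssc-miR-218 and ssc-miR-218b, and ssc-miR-9 and ssc-miR-9-1 are such pairs, and values of family members that share reads are uncertain. Alternatives covered scaling (RLE, upper-quartile and TMM factors), filters, the test (DESeq2 1.42.0, limma-voom and edgeR on recovered reads), the feature set, the pseudocount (0.1 and 10), the threshold and leaving out each library. The runs of edgeR on recovered reads, TMM factors in limma and the pseudocounts were added after seeing the data, although the design had named edgeR with TMM for counts. Figures were drawn with matplotlib 3.10.9.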

Results

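Small RNA of skin from Xiang pigs, a small Chinese breed of Sus scrofa, was sequenced in 6 libraries. Of these, 3 came from black skin (S03, S04 and S05) and 3 from white skin (S02, S06 and S07). The table lists 898 microRNAs (miRNAs), of which 280 carry a miRBase-style porcine name and 618 carry a predicted identifier. The values are RPM, that is reads scaled to a total of 1e+06 per library, and whole reads could be recovered from them, between 6454685 (S06) and 10165949 (S07) per library. Reads per library did not separate the groups (two-sided exact permutation p = 1). At least 1 read was found for 816 ± 11.5 miRNAs in white skin and 803 ± 6 in black skin (SD, n = 3 each). The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

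A small set of miRNAs made up most of each library, led on average by ssc-miR-21 and the predicted unconservative_AEMK02000452.1_1853219. The 10 most abundant held 67.7 ± 1.75% of the reads in white skin and 71.4 ± 1.67% in black skin (SD, n = 3), with no overlap between the groups. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. For the 5 most abundant the direction turned, with a share 1.93 points lower in black skin (difference -1.93, exact permutation p = 0.5). ssc-miR-143-3p, among the 10 but not the 5, alone rose by more than the whole difference of the 10. Among named miRNAs ssc-miR-21 held 12.4% of the reads on average, ssc-miR-148a-3p 11.3% and ssc-miR-27b-3p 9.02%, and none of the 3 passed the test between the groups (limma, adjusted p = 0.730, 0.327 and 0.754). The other named miRNAs of the 10 were ssc-let-7i, ssc-let-7g, ssc-miR-143-3p, ssc-miR-26a, ssc-miR-99a and ssc-miR-126-3p. The predicted miRNA among them held 13.7 ± 1.81% of the reads in white skin and 9.03 ± 1.01% in black skin (SD, n = 3), and the difference missed the threshold (limma, adjusted p = 0.0629). It passed with TMM factors (0.0463), no filter (0.0485), a filter of 10 RPM in 3 libraries (0.0473) and limma-voom (0.0447). ssc-miR-26a (0.53, adjusted p = 0.148) passed without S02 (0.0237). Predicted identifiers together held 17.1 ± 2.03% in white skin and 11.8 ± 1.23% in black skin (SD, n = 3, two-sided exact permutation p = 0.1). Without the most abundant of them, named above, they held 3.43 ± 0.220% in white and 2.80 ± 0.292% in black skin (SD, n = 3, exact permutation p = 0.1). Libraries of 1 group resembled each other more than those of the other group. Spearman correlations across miRNAs were 0.961 to 0.973 within black skin, 0.942 to 0.960 within white skin and 0.908 to 0.941 between the groups. The first principal component, with 50.9% of the variance, separated the groups, and the second, with 20.3%, set the white library S02 apart at -9.24 against 2.77 and 6.10 for the other white libraries.

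The series asks which miRNAs bear on melanin formation, and it names ssc-miR-221-3p, studied there as a regulator of TYRP1, an enzyme of melanin synthesis. This miRNA was lower in black skin. It measured 614.5, 1147 and 974.2 RPM in the white libraries S02, S06 and S07, and 424.1, 334.1 and 362.9 RPM in the black libraries S03, S04 and S05. The group means were 912 ± 272 and 374 ± 46.0 RPM (SD, n = 3), a 2.44-fold lower level in black skin. On the log2(RPM + 1) scale the difference was -1.24 with a standard error of 0.25 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0318), and the groups did not overlap (two-sided exact permutation p = 0.1). The call held without S02 (-1.50, adjusted p = 0.00468) and was lost on leaving out S03 (adjusted p = 0.0520), S04 (0.0731), S05 (0.0898), S06 (0.108) or S07 (0.0672).

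The other products of the same locus did not pass the test. ssc-miR-221-5p, the opposite arm of the hairpin, measured 149.8 ± 11.7 RPM in white and 116 ± 13.8 RPM in black skin (SD, n = 3; difference -0.37, adjusted p = 0.310). ssc-miR-222, from the neighbouring precursor, measured 455 ± 153 RPM in white and 268 ± 61.9 RPM in black skin (SD, n = 3; -0.73, adjusted p = 0.152), with overlap between the groups. In Sscrofa11.1 the precursors lie on chromosome X at 40571068 to 40571137 (MIR221) and 40571808 to 40571887 (MIR222), outside annotated genes. The log2 ratio of the 3p to the 5p arm of miR-221 was 2.55 ± 0.35 in white and 1.68 ± 0.16 in black skin (SD, n = 3). This difference of -0.88 (standard error 0.26) passed the test among 40 arm pairs (limma, adjusted p = 0.0439), of which 5 did.

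**Figure D1:**
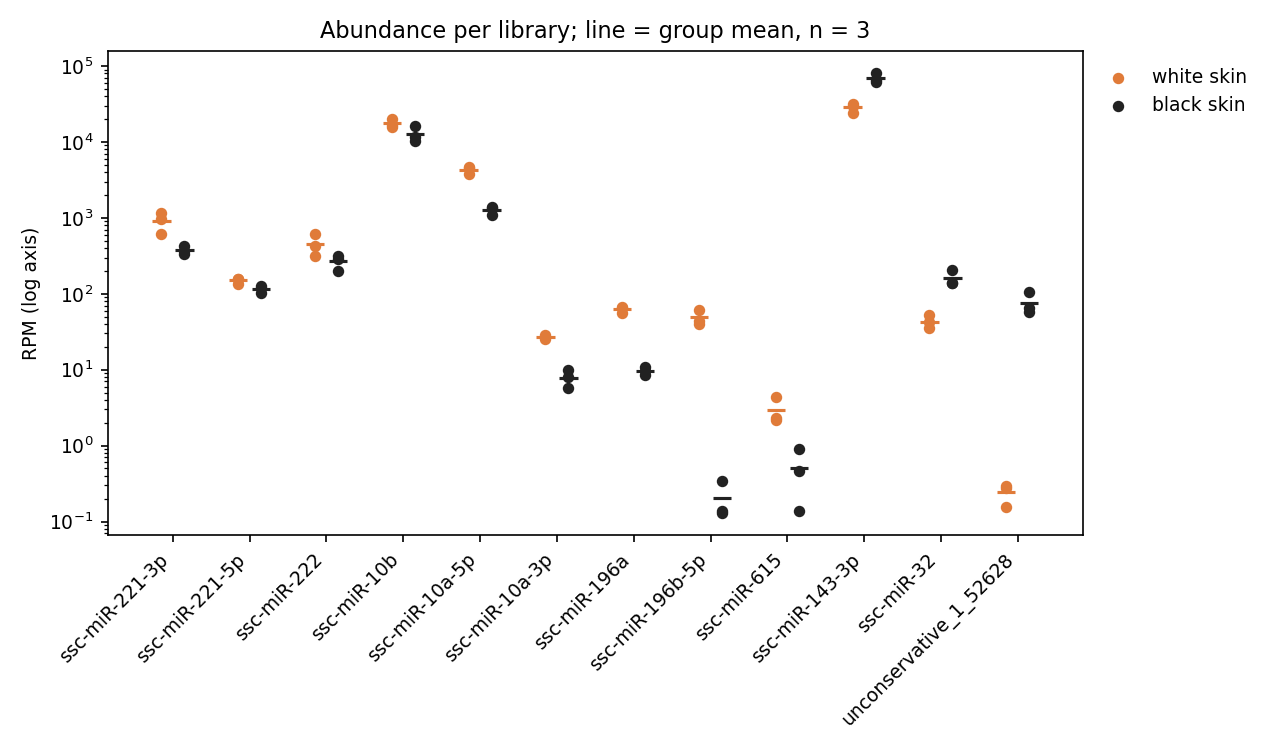
RPM (log axis) of 12 miRNAs in each of the 3 white and 3 black skin libraries, 1 point per library, with a line at each group mean. ssc-miR-221-3p lies between 334.1 and 424.1 RPM in black skin and between 614.5 and 1147 RPM in white skin, and ssc-miR-196b-5p and unconservative_1_52628 are each near absent from 1 group.

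Over all miRNAs, 32 of the 454 tested (7.05%) differed between black and white skin at an adjusted p under 0.05 (limma), 18 of them higher and 14 lower in black skin. Among the 242 with a miRBase-style name, 15 were higher and 11 lower. Among the 212 predicted ones, 3 were higher and 3 lower. Among called miRNAs with a name, ssc-miR-196b-5p had the largest fall and ssc-miR-142-3p the largest rise on the log2(RPM + 1) scale, and unconservative_1_52628 had the largest change of all 32. All 32 had no overlap between the groups, as had 124 of the 454 tested (27.3%), where chance gives 10%. At an unadjusted p under 0.05 there were 116. With predicted miRNAs left out before scaling, the calls were 16 higher and 19 lower, and edgeR on the recovered reads called 30, with 13 higher and 17 lower. DESeq2 on those reads called 34 higher and 19 lower. Leaving out 1 library gave 41 calls without S02, 9 without S03, 18 without S04, 7 without S05, 7 without S06 and 14 without S07. The 6 calls that held in all of these fits were ssc-miR-196b-5p, ssc-miR-196a, ssc-miR-10a-5p, ssc-miR-143-3p, ssc-miR-32 and unconservative_1_52628.

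**Figure D2:**
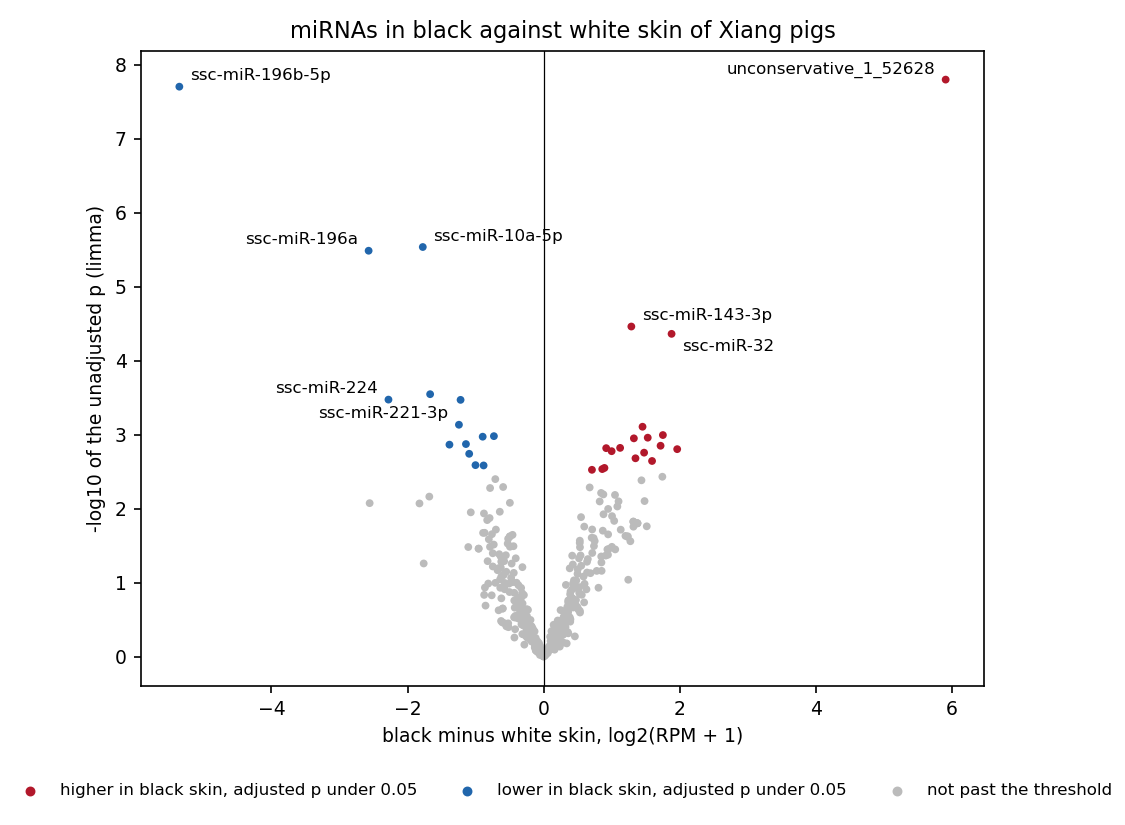
Difference between black and white skin on the log2(RPM + 1) scale (x axis) against -log10 of the unadjusted limma p (y axis) for 454 tested miRNAs, 1 point each. The 18 miRNAs called higher and the 14 called lower in black skin are coloured, and ssc-miR-196b-5p (-5.35) and unconservative_1_52628 (5.91) lie farthest from 0.

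Most miRNAs of the HOX clusters, gene groups that set position along the body axis, were lower in black skin. Of 6 tested members 5 fell, and 6 fell when adjusted over the list alone, with a median of -1.72. ssc-miR-196b-5p was close to absent, with 5 reads in the 3 black libraries against 1148 in the 3 white ones, a ratio of 228 (95% counting interval 97.3 to 703, counting error only). ssc-miR-196a was 6.45-fold lower, at 9.65 ± 1.15 RPM in black and 62.2 ± 5.92 RPM in white skin (SD, n = 3; -2.57, adjusted p = 0.000371). ssc-miR-10a-5p was 3.43-fold lower, at 1266 ± 151 RPM against 4336 ± 513 RPM (SD, n = 3; -1.78, adjusted p = 0.000371), and its opposite arm ssc-miR-10a-3p fell with it (-1.67, adjusted p = 0.0171). ssc-miR-615, a scarce miRNA at 2.94 ± 1.21 RPM in white and 0.501 ± 0.385 RPM in black skin (SD, n = 3), also fell (-1.38, adjusted p = 0.0324). The abundant ssc-miR-10b measured 17592 ± 2028 RPM in white and 12658 ± 3006 RPM in black skin and did not pass the test over all miRNAs (SD, n = 3; -0.49, adjusted p = 0.154). The list stood apart from the other miRNAs (camera with a preset correlation of 0.01, adjusted p = 1.61e-08), also with an estimated correlation (adjusted p = 0.0436). That estimate was negative (-0.0866), so the second test made no allowance for members that move together, such as the arms of miR-10a. Without 1 library, the call of ssc-miR-10a-3p was lost for S03 (adjusted p = 0.0502), S05 (0.0698) and S06 (0.0644), and that of ssc-miR-615 was lost for S03 (0.0520), S04 (0.0904), S05 (0.113), S06 (0.116) and S07 (0.0574), and with a pseudocount of 10 (0.0582).

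Apart from the arms of miR-10a, which share a precursor, the members with a matched precursor come from separate loci. In Sscrofa11.1, MIR10A lies on chromosome 12 at 24833644 to 24833723 between HOXB3 and HOXB5, and MIR196A-1 on the same chromosome at 24886316 to 24886395 between HOXB8 and HOXB13. MIR196A-2 lies on chromosome 5 at 19204442 to 19204548 beside HOXC10, and MIR615 at 19246763 to 19246850 within HOXC5. MIR10B lies on chromosome 15 at 81951644 to 81951723 beside HOXD3. No precursor of ssc-miR-196b-5p was matched in the annotation used here.

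**Figure D3:**
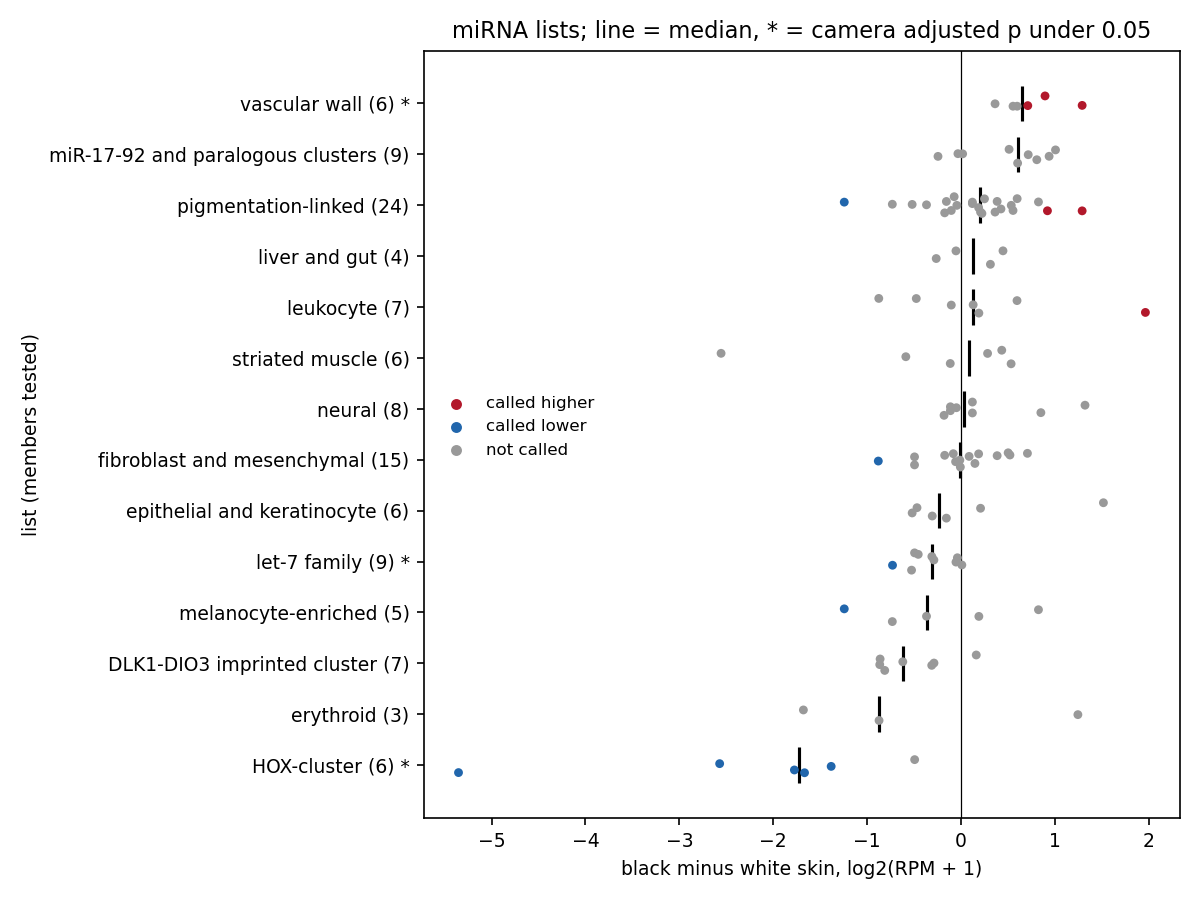
Difference between black and white skin on the log2(RPM + 1) scale for the tested members of 14 miRNA lists, 1 point per miRNA and a line at each list's median, with the number of tested members in brackets. The HOX-cluster list has the lowest median (-1.72) and the vascular wall list the highest (0.65).

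Some miRNAs known from the vessel wall rose in black skin. Of 6 tested members of the vascular wall list 3 rose, and 4 rose when adjusted over the list alone, with a median of 0.65 and all 6 values above 0. These are both arms of miR-126, miR-143 and miR-145, and the last 2 have neighbouring precursors, so the 6 values are not independent. ssc-miR-143-3p, enriched in smooth muscle, was 2.45-fold higher, at 69866 ± 10297 RPM against 28574 ± 3838 RPM in white skin (SD, n = 3; 1.29, adjusted p = 0.00314). The 2 arms of the endothelial miR-126 rose less, ssc-miR-126-5p by 0.89 and ssc-miR-126-3p by 0.71 (adjusted p = 0.0423 for both). ssc-miR-145-5p, transcribed beside miR-143, measured 2248 ± 870 RPM in black and 1676 ± 140 RPM in white skin (SD, n = 3; 0.36, adjusted p = 0.433). The list passed camera (adjusted p = 0.00122) but not with an estimated correlation (adjusted p = 0.396). The calls of miR-126 depended on the setting. ssc-miR-126-3p was lost with edgeR (adjusted p = 0.0795), DESeq2 (0.129), limma-voom (0.0689), RLE factors (0.0767), TMM factors (0.0666) and a pseudocount of 10 (0.0555), and ssc-miR-126-5p with edgeR (0.0528), limma-voom (0.0501) and no filter (0.0852). ssc-miR-143-3p kept its call without each of the 6 libraries in turn, and each arm of miR-126 did so in 1 of these 6 fits, with adjusted p up to 0.159.

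The other named miRNAs that rose span a wide range of abundance. ssc-miR-142-3p, made by blood cells, was 3.87-fold higher at 190 ± 78.5 RPM against 49.1 ± 24.2 RPM, and ssc-miR-32 was 3.76-fold higher at 162 ± 37.8 RPM against 43.1 ± 8.35 RPM (SD, n = 3; adjusted p = 0.0324 and 0.00328). ssc-miR-27a rose 1.92-fold to 11228 ± 2880 RPM and ssc-miR-374a-5p 1.94-fold to 985 ± 33.0 RPM (SD, n = 3; adjusted p = 0.0324 and 0.0329). Neighbouring precursors on chromosome X gave ssc-miR-450c-5p, ssc-miR-542-3p and ssc-miR-450a, higher by 1.59, 1.53 and 1.45 on the log2 scale. They are scarce, and with a pseudocount of 10 these differences were 0.73, 0.91 and 0.45. ssc-miR-193a-3p was higher by 1.48, or by 0.75 with a pseudocount of 10. It is the scarcer arm, with a log2 ratio to ssc-miR-193a-5p of -5.1 in white and -3.3 in black skin. This ratio rose by 1.87, more than the arm itself, so ssc-miR-193a-5p did not rise. ssc-miR-24-2-5p was 1.82-fold higher at 153 ± 15.8 RPM against 84.1 ± 10.7 RPM (SD, n = 3; adjusted p = 0.0423). The scarce ssc-miR-135, ssc-miR-490 and ssc-miR-7143-3p rose by 1.35, 1.33 and 1.12, from means of 0.549, 1.19 and 0.377 RPM in white skin, and at such levels the log2(RPM + 1) scale understates the change. The call of ssc-miR-135 was lost with edgeR (adjusted p = 0.0829), limma-voom (0.0769) and a pseudocount of 0.1 (0.0896), that of ssc-miR-450c-5p with edgeR (0.0582), and that of ssc-miR-7143-3p with a pseudocount of 10 (0.0681). Without each library in turn ssc-miR-32 kept its call, and the others lost theirs in 3 (ssc-miR-142-3p), 5 or 6 (ssc-miR-450c-5p and ssc-miR-24-2-5p) of 6 fits. With all libraries ssc-miR-24-2-5p kept its call in 8 of 13 other settings.

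Besides the HOX-cluster miRNAs and ssc-miR-221-3p, 5 named miRNAs fell in black skin. ssc-miR-224 was 4.92-fold lower at 8.38 ± 5.29 RPM against 41.3 ± 11.4 RPM, and ssc-miR-320 was 2.36-fold lower at 123 ± 15.6 RPM against 290 ± 56.2 RPM (SD, n = 3; adjusted p = 0.0171 for both). ssc-miR-181b fell by 1.09 and ssc-miR-214, a mesenchymal miRNA, fell by 0.88 (adjusted p = 0.0329 and 0.0408). Both calls were lost with no filter on low counts (adjusted p = 0.0501 and 0.0845). Without 1 library at a time, these 4 and ssc-let-7c lost their calls in 3 to 5 of 6 fits, with adjusted p up to 0.159. ssc-let-7c was 1.65-fold lower, at 18237 ± 2240 RPM against 30161 ± 2110 RPM (SD, n = 3; -0.73, adjusted p = 0.0318). It was the 1 called member of 9 in the let-7 family list, of which 2 fell when adjusted over the list alone, with a median of -0.31. The abundant ssc-let-7i (-0.53, adjusted p = 0.150) and ssc-let-7g (-0.31, adjusted p = 0.221) did not pass, although ssc-let-7i did without S02 (0.0418). The let-7 list passed camera (adjusted p = 0.0146) but not with an estimated correlation (adjusted p = 0.411) or without S07 (adjusted p = 0.0693), and the near-identical let-7 sequences can exchange reads.

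The predicted unconservative_1_52628 was present in black skin and close to absent in white skin. It measured 65.6, 57.0 and 106 RPM in S03, S04 and S05 and 0.274, 0.155 and 0.295 RPM in S02, S06 and S07. Its reads numbered 1839 in black and 6 in white skin, a ratio of 309 (95% counting interval 142 to 843), and the difference was 5.91 (standard error 0.32, adjusted p = 4.5e-06). unconservative_6_663466 also rose, by 1.75, and its values equalled those of unconservative_1_93424 in 5 of 6 libraries, so whether they are separate miRNAs is uncertain. unconservative_6_683512 fell by 1.14 and unconservative_3_403490 was 2.02-fold lower. The last of these lost its call with no filter (adjusted p = 0.0712), and unconservative_6_663466 with a pseudocount of 10 (0.0582). Leaving out 1 library at a time, unconservative_1_52628 kept its call in all 6 fits, while the other 3 lost theirs in 4 or 5, with adjusted p up to 0.156.

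The lists linked to pigment cells moved in no common direction. Of 24 tested members of the pigmentation-linked list 2 rose (ssc-miR-143-3p and ssc-miR-27a), 1 fell (ssc-miR-221-3p) and 21 did not pass, and 3 rose and 1 fell when adjusted over the list alone (median 0.20, camera adjusted p = 0.413). Its most abundant members, ssc-miR-21 and ssc-miR-148a-3p, gave differences of 0.19 and 0.42. In the melanocyte-enriched list 1 of 5 fell (ssc-miR-221-3p), and adjusted over the list alone 1 rose and 1 fell (median -0.37, camera adjusted p = 0.512). This list has 10 names, and some, such as miR-211, had no product among the miRNAs listed. Its tested members include ssc-miR-221-3p, ssc-miR-221-5p and ssc-miR-222 from 1 locus, so it is a narrow measure of pigment cells. Its members ssc-miR-204 and ssc-miR-146a-5p gave 0.82 (adjusted p = 0.0804) and 0.19 (adjusted p = 0.744).

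Apart from the vascular wall list, the lists for other cell types in skin did not pass camera. None of 6 epithelial and keratinocyte miRNAs was called (median -0.23, mean 0.04, adjusted p = 0.689), with ssc-miR-205 at -0.47, ssc-miR-182 at -0.52 and ssc-miR-183 at -0.16. That list has 13 names, and miR-203 and miR-141 were among those with no product listed. Its members ssc-miR-182, ssc-miR-183 and ssc-miR-96-5p come from neighbouring precursors. Of 15 fibroblast and mesenchymal miRNAs 1 fell (ssc-miR-214), also when adjusted over the list alone, and the median was -0.01 and the mean 0.02 (adjusted p = 0.946), with ssc-miR-99a at -0.01 and ssc-miR-100 at 0.15. Of 6 striated muscle miRNAs none was called (median 0.08, mean -0.34, adjusted p = 0.841), with ssc-miR-1 at -0.12, ssc-miR-378 at -0.59 and ssc-miR-499-5p at 0.43. The muscle miRNA ssc-miR-206 varied inside the white group, with 12.6 RPM in S02, 106 in S06 and 115 in S07, against 4.77 to 14.6 RPM in black skin (difference -2.56, adjusted p = 0.0804). Among 7 leukocyte miRNAs 1 rose (ssc-miR-142-3p), 1 rose and 1 fell when adjusted over the list alone, and the median was 0.13 (adjusted p = 0.946), with ssc-miR-142-5p at 0.60, ssc-miR-146a-5p at 0.19 and ssc-miR-146b at -0.48. None of 3 erythroid miRNAs was called over all miRNAs and 1 fell when adjusted over the list alone (median -0.87, adjusted p = 0.606). ssc-miR-451 ranged from 981 to 4248 RPM in black and from 1688 to 4855 RPM in white skin, while ssc-miR-486 gave -1.68 (adjusted p = 0.0743) and ssc-miR-144 gave 1.24 (adjusted p = 0.284). ssc-miR-486 passed with DESeq2 (adjusted p = 0.0113), with miRBase-style names only (0.0341) and without S05 (-2.28, 0.00924).

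The remaining 4 lists had no called member, also when adjusted over the list alone. Their medians were 0.03 for the 8 neural miRNAs (adjusted p = 0.731), 0.13 for the 4 of liver and gut (0.785), 0.60 for the 9 of miR-17-92 and its paralogous clusters (0.202) and -0.62 for the 7 of the DLK1-DIO3 imprinted cluster (0.163). Among their abundant members, ssc-miR-7 gave -0.05, ssc-miR-218 0.12, ssc-miR-192 0.45, ssc-miR-20a 0.02, ssc-miR-92a -0.25, ssc-miR-17-5p -0.03, ssc-miR-127 -0.81 and ssc-miR-493-5p -0.86, none past the threshold. The liver miRNA ssc-miR-122 was at 121 RPM in the black library S05 and at 8.52 and 11.6 RPM in S03 and S04. The DLK1-DIO3 list passed without S06 (adjusted p = 0.0392) or S07 (0.0385) and the miR-17-92 list without S04 (0.0225).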

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

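The runs of edgeR on recovered reads, TMM factors in limma and both pseudocounts were added after the data were seen. The design had named edgeR with TMM for a table of counts. The count of 32 changed miRNAs stayed between 27 and 36 under 12 settings of scaling, filter, feature set, pseudocount, limma-voom and edgeR, of which 23 to 32 were shared with the main test. It was 53 with DESeq2 (34 higher, 31 of the 53 shared), 53 at an adjusted p under 0.1 and 51 at an unadjusted p under 0.05 with a log2 fold change of at least 1; the cause was not tested for DESeq2, the second is looser by construction, and the third shared 24 of its 51 calls with the main test. An adjusted p under 0.05 with a log2 fold change of at least 1 left 24. Library size alone is the main scaling and was not a separate setting. Leaving out 1 library, with fewer samples, gave 7 to 41 calls (3 to 23 higher, 3 to 18 lower), and 6 of the 32 calls held in all 6 such fits. No called miRNA changed sign in any setting. Leaving out a library could not have changed one, since all 32 had no overlap between the groups. ssc-miR-221-3p ranged from -1.50 to -1.06 and kept its call in 13 settings with all libraries, but in 1 of 6 with a library left out. The count of lists past the threshold was 3 and fell to 1 with an estimated correlation. The HOX-cluster list held in 18 of 18 settings. With miRBase-style names only the median over the 242 named miRNAs was -0.137, against 0.00218 over all 454 in the main test, and both membership and scaling changed. Scaling alone moved ssc-miR-221-3p from -1.24 to -1.33, ssc-miR-143-3p from 1.29 to 1.20 and ssc-miR-27a from 0.919 to 0.830. These shifts are smaller than that of the median. The higher share of the 10 most abundant miRNAs in black skin (3.66 points) reversed to -1.93 for the 5 most abundant (exact permutation p = 0.5). ssc-miR-143-3p, among the 10 but not the 5, alone rose by more than 3.66 points, so the other members of the 10 together did not rise. The excess of correlation within over between groups was 0.0324 and moved to 0.0195 with no filter and 0.0144 with Pearson correlations. Other named miRNAs gave 1085 values on the same side of the threshold, 120 that lost and 9 that gained the call. At this depth 3 reads are 0.295 to 0.465 RPM, which limits what can be said of ssc-miR-196b-5p in black skin and unconservative_1_52628 in white skin.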

Other observations

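The lists, the other scalings except TMM and the counts over other splits were fixed before the data were examined. The explanations and the tests set against them were chosen after the results were seen, as were the arm ratios and the tests of neighbouring precursors. Several miRNAs from neighbouring precursors on chromosome X rose in black skin. Of 5 tested products of the miR-424, miR-503, miR-542 and miR-450 cluster 3 rose (ssc-miR-450a, ssc-miR-542-3p and ssc-miR-450c-5p), all 5 lay above 0 and the median was 1.45. The cluster was picked because these 3 had been seen to rise, so no test of it as a group is given. All 3 are scarce, and a pseudocount of 10 reduced their differences to 0.45, 0.91 and 0.73. Of 29 tested named miRNAs with precursors on chromosome X 6 were called (20.7%), 4 higher and 2 lower, against 17 of 197 (8.63%) on other chromosomes, a difference that did not pass (Fisher's exact p = 0.0906). The comparison covered 226 of the 242 tested named miRNAs. Those left out include the called ssc-miR-196b-5p, with no matched precursor, and the 2 called arms of miR-126, with no placed precursor. They also include 3 tested miRNAs with precursors on X and elsewhere. Clustered miRNAs are not independent. Over 37 pairs of precursors within 10 kb of each other, 67.6% of pairs differed in the same direction, against 49.9% after shuffling (permutation p = 0.0303). The cluster seen to rise gave 6 of these pairs, and without its miRNAs 19 of 31 pairs agreed (61.3%, against 50.0% after shuffling, permutation p = 0.142), so a wider pattern was not shown. The mean absolute difference between the log2 fold changes of a pair was 0.625, against 0.737 after shuffling (permutation p = 0.171), so the pairs were not shown to change by like amounts.

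The arms of some hairpins moved apart. The 3p to 5p log2 ratio rose in black skin for miR-193a (1.87, limma adjusted p = 0.000745) and miR-142 (1.37, adjusted p = 0.00406). It fell by 1.49 for miR-455 (adjusted p = 0.00406), by 1.34 for miR-27b (adjusted p = 0.0283) and by 0.88 for miR-221 (adjusted p = 0.0439). ssc-miR-455-3p measured 230 ± 31.0 RPM in white and 146 ± 11.7 RPM in black skin, while ssc-miR-455-5p measured 765 ± 247 and 1338 ± 172 RPM (SD, n = 3).

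The fall of the HOX-cluster miRNAs in black skin was set against 4 explanations. Scaling is argued against: the list's median stayed at -1.71 or lower under 5 other scalings. For less dermal tissue or less muscle, the values argue only against a loss that lowers all members of the tissue's list alike. The fibroblast and mesenchymal median was -0.00822 (SD 0.43 over members) and the striated muscle median 0.0831 (SD 1.16). Such a loss would need the members to fall together by about the HOX-cluster median of -1.72. These medians do not decide on a loss seen only in members particular to the tissue. In the fibroblast and mesenchymal list the called member ssc-miR-214 gave -0.88. For muscle the mean was -0.336 and ssc-miR-206 alone fell further, by 2.56 (standard error 0.76, not called), while ssc-miR-1, the most abundant muscle member, gave -0.12 (standard error 0.48). A different body position of the skin samples stays open, since the labels give no site and colour and position cannot be told apart. That explanation predicts a further fall of miR-196 than of miR-10. The mean log2 fold change of miR-196 minus that of miR-10 was -2.65 (standard error 0.13), -1.26 without ssc-miR-196b-5p and -1.09 with a pseudocount of 10. This is the predicted direction, but the prediction was written after these values had been seen, so they cannot count as support.

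The fall of ssc-miR-221-3p beyond that of ssc-miR-221-5p was set against a shift of all 3p arms relative to 5p arms. The median change of the ratio over 40 arm pairs was -0.0257 (SD 0.65), far from the -0.88 of miR-221, so a general arm shift is argued against. A bias in ligation or mapping that depends on sequence was not tested and stays open beside a biological difference between black and white skin.

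The rise of unconservative_1_52628 was set against a larger melanocyte share in black skin. The melanocyte-enriched list had a median of -0.369 with an SD of 0.80 over 5 members that went both ways, so the list does not decide it. A variant that differs between the animals and removes reads from white skin was not tested, as the table gives no sequence, and a link to skin colour stays open as well.

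With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 32 calls, with 18 higher and 14 lower, and the highest of the other splits gave 1 call. In each of these 3 counts 1 of the 10 splits, the real one, reached the real value. For lists past the threshold the real value was 3 and the highest other split gave 5, so 2 of the 10 splits gave as many. The other splits passed 0, 1, 2, 0, 2, 5, 1, 2 and 2 lists, so most of them passed a list.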
